A study of Homo sapiens and Drosophila melanogaster with 29 samples.

How the data were processed

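Gene expression was measured by RNA sequencing in 29 libraries. They were 12 libraries of whole fruit flies (Drosophila melanogaster), 9 of HEK293T cells carrying a blank vector or overexpressing SF3B3 or SF3B4, 6 of 293T cells that were wild type or overexpressed SF3B3-MMS1, and 2 of 293T cells treated with NAI-N3 or DMSO for 10 min. HEK293T and 293T are names of 1 human embryonic kidney cell line. The meaning of MMS1 is not given in the sources used here. Groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

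Reads were handled with cutadapt 1.15 and STAR, and the builds were hg38 for human and dm6 for fly libraries, per the submitters' processing notes, which give neither the role of each tool nor the version of STAR. The program that counted genes, its use of strand and the gene annotation are not given in the sources used here. The authors deposited 1 table per library with the position of each gene and its Coverage, FPKM and TPM. Coverage is a mean signal of aligned bases per position of the gene, per the file headers and the values. FPKM values are scaled to gene length and to the aligned total, per the file headers. The deposited TPM values are scaled to the same total in each library. The values are not read counts, so no count model was used. Depth was computed as the deposited Coverage divided by FPKM, which returns the aligned bases behind each table. It was 5.57 to 9.99 gigabases in the fly libraries and 5.5 to 7.21 in the HEK293T libraries. The 293T libraries had 17.5 to 22 gigabases apart from SF3B3-MMS1 replicate 2 with 1.82. The NAI-N3 and DMSO libraries had 6.68 and 1.73 megabases. Human tables held 43390 gene identifiers, which were summed to 39576 symbols, 1755 of them with more than 1 identifier. Fly tables held 17791 identifiers.

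Values were tested as log2(TPM + 1), so a fold change understates the change of weakly expressed genes. Genes with a TPM of at least 1 in at least 3 libraries of the fit were kept. Each comparison was tested with limma-trend (limma 3.58.1 in R 4.3.3), two-sided, with 1 mean per group and 1 spread estimate for all groups of an experiment, and with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists with at least 3 tested members, and again with the estimated correlation and with fry. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The procedure was tested on simulated data in which 200 genes were changed by known folds. The changed genes had a mean level above that of 5 TPM, and the noise was independent between genes. Recovery of weaker genes was therefore not measured, and the male fly comparison was not simulated. For the female fly comparison (13675 genes), 13.4% of changes of 1.5-fold, 58.2% of 2-fold and 89.4% of 4-fold were recovered. For the SF3B3 comparison (15993 genes) the shares were 83.6%, 97% and 100%, and for the SF3B3-MMS1 comparison (15558 genes) 80.6%, 92.5% and 97%.

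The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the targeted gene and the SF3b complex, the 10 called genes with the largest rise and the 10 with the largest fall, and up to 4 called members of each list that passed or had at least 3 called members. A gene in the second part of the rule had a mean of at least 5 TPM in the higher group, no overlap between the libraries of the groups, and a gene symbol. A gene at 0 throughout a compared group was left out of the ranking by fold, a choice made after the data were examined, because the tables list some abundant genes at exactly 0 in single libraries. The text gives a part of the named genes. For the human libraries, XIST was left out of the named genes and Y-linked genes out of the windows of neighbouring genes, but neither out of the tests. Of the 28 human lists, 27 had matching names, and the list of mitochondrially encoded proteins had none. The fly tables pair no gene names with their identifiers and the reference table used here holds human genes, so the 37 fly lists and the fly Sf3b3 gene are not analysed here by name. At most 2 rising and 2 falling fly identifiers are given per comparison.

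The alternatives were a pseudocount of 0.1, a filter of 5 TPM or none, FPKM in place of TPM, rescaling by the median of ratios to the geometric mean of each gene, rescaling without the 100 highest genes, robust and precision-weighted fits, the replicate number as a block, fits with only the compared groups, and leaving out each replicate in turn. Added after the data were examined were fits without genes at 0 throughout a compared group, human fits without summing by symbol, rescaled fits without single libraries, and the comparison of SF3B4 with SF3B3-MMS1 overexpression. The analyses of fly chromosomes, of genes listed at 0, of female transcripts in male libraries and of neighbouring genes were also chosen then. Other splits of the same libraries were refitted, all 10 for 3 against 3 libraries and 100 drawn ones for 12 libraries.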

Results

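Expression was profiled in whole flies that were wild type (WT) or carried an Sf3b3 allele lacking a poison exon (PE-), an exon whose inclusion leads to a premature stop, with 3 libraries per sex and genotype. A PE- effect below means the difference between PE- and WT flies. Whether these flies shared a genetic background was not examined, so the allele cannot be told apart from other differences between them. Expression was also profiled in HEK293T cells with a blank vector, SF3B3 overexpression or SF3B4 overexpression, and in 293T cells that were WT or overexpressed SF3B3-MMS1, with 3 libraries per group. SF3B3 and SF3B4 belong to the SF3b complex, the part of the U2 snRNP that binds the branch site of introns. Genes at 1 TPM or more numbered 9291 to 9664 in female and 12740 to 13203 in male fly libraries, 14653 to 15848 in the HEK293T libraries and 15075 to 15395 in the 293T libraries. Replicates correlated across genes at 0.964 to 0.974 in females, 0.894 to 0.947 in males and 0.977 to 0.996 in the human groups.

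In PE- females, FBgn0035162 (dm6, 3L 826720 to 833385) rose from 84.3 ± 14.4 TPM in WT to 500 ± 24.8 (SD, n = 3 each), a log2 change of 2.57 (SE 0.25, limma adjusted p = 0.000577). FBgn0266694 (3L 826720 to 830190), which lies within the span of FBgn0035162 and whose reads are uncertain for that reason, rose from 0.325 ± 0.232 to 18.7 ± 1.03 TPM. FBgn0033027 (2R 5503437 to 5507866) fell from 22.5 ± 10.2 to 0.607 ± 0.318 TPM, with a log2 change of -3.79 (SE 0.29, limma adjusted p = 0.00013). FBgn0040705 (2L 4454626 to 4455207) was at 20.8, 16.4 and 14.9 TPM in the WT libraries and at 0.272 TPM or listed at 0 in the PE- libraries. In total 85 of 13675 tested genes passed, 18 higher and 67 lower in PE- females, and 15 of the higher and 63 of the lower genes changed at least 2-fold. The count was 193 after median-of-ratios rescaling (60 higher and 133 lower) and 242 after rescaling without the 100 highest genes. It was 159 with FPKM and 144 with only the female libraries in the fit.

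In PE- males, FBgn0264787 (3R 6408978 to 6409578) was at 28.6, 30.5 and 25.5 TPM, against 0.241 TPM in 1 WT library and a listing at 0 in the others (log2 change 4.76, SE 0.15, limma adjusted p = 4.38e-08). FBgn0015714 (2R 14873953 to 14875739) was at 28.4, 25.3 and 15.4 TPM in WT males and at 1.19, 0.994 and a listed 0 in PE- males (log2 change -3.84, limma adjusted p = 9.19e-05). FBgn0033027 fell in males too, from 22.5 ± 4.1 to 2.41 ± 0.11 TPM, by 2.77 on the log2 scale. FBgn0035162 was at 26.2 ± 6.52 TPM in WT and 22.4 ± 7.23 in PE- males, which did not pass (limma adjusted p = 0.537). Of the tested genes 2160 passed, 1588 higher and 572 lower, and rescaling by the median of ratios gave 3018 higher and 929 lower. Of the 29 tested Y-chromosome genes 11 were higher and 0 lower in PE- males, with a median log2 change of 0.49. Without WT replicate 3, which stands apart as described below, 5 of 29 were higher and 0 lower, with a median of 0.31. Leaving out any other male library gave 5 (PE- replicate 2 or 3) to 15 (WT replicate 2) higher and 0 lower, with medians of 0.28 to 0.68. On all libraries the median was 0.59 after rescaling, and over chromosomes 2 and 3 it was -0.01, or 0.07 rescaled. The count of 2160 fell to 1347 without WT replicate 1, where the balance turned to 638 higher and 709 lower, and was 2994 without WT replicate 2 (2650 higher and 344 lower). It was 893 without WT replicate 3 (556 higher and 337 lower), 794 without PE- replicate 2 and 1046 without PE- replicate 3. It was 795 with a pseudocount of 0.1, 3774 with FPKM and 3793 after rescaling without the 100 highest genes. With only the male libraries in the fit it was 88. The main fit pools the spread with the female libraries, whose replicates correlated more closely (0.964 to 0.974 against 0.894 to 0.947). Of the tested genes 2408 were at 0 throughout a female group, which adds no spread for them. The adjusted p-values and the count of 2160 in males may therefore be too liberal.

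WT male replicate 3 held more female-abundant transcripts than the other WT males. Over 40 genes with at least 100 TPM in females and little in PE- males, it stood at a median of 18.2% of the female level (quartiles 16.5% and 78.8%, highest 402%). The medians were 0.118% and 0.0965% in WT males 1 and 2. Those of the PE- males, 0.19% or less, were set by the choice of genes. After rescaling and without that library, 3837 genes passed in males. A mitochondrial gene that held 18.1% to 24% of TPM in 9 fly libraries was listed at 0 in female WT replicate 2, male WT replicate 2 and male PE- replicate 2, which changes the TPM of all other genes in those libraries.

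Averaged over the sexes, FBgn0026315 (3R 11170817 to 11172664) rose by 1.78 on the log2 scale (SE 0.15, limma adjusted p = 0.000124), from 1.33 ± 0.474 to 7.27 ± 1.47 TPM in females and from 3.19 ± 0.455 to 13.1 ± 3 in males. FBgn0015714 and FBgn0033027 had log2 changes of -3.54 and -3.28. In all, 459 genes passed, 227 higher and 232 lower. After median-of-ratios rescaling 3017 passed, 2338 higher and 679 lower. The count was 2421 without male WT replicate 2 (2062 higher and 359 lower), so the balance of directions depended on the scaling and on single libraries. It was 240 and 230 without female WT replicates 2 and 3, 225, 237 and 274 without female PE- replicates 1, 2 and 3, and 246 without male PE- replicate 3. FPKM gave 2621 and rescaling without the 100 highest genes 2349, and 242 passed without the genes at 0 throughout a group.

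The PE- effect differed between the sexes for FBgn0035162 (log2 difference, male minus female, -2.81, SE 0.35, limma adjusted p = 0.00354), which rose in females and did not pass in males. FBgn0034328 was at 49.4, 55 and 51.7 TPM in WT and 43.3, 28.5 and 47.8 in PE- females, and at 19.6, 25.5 and 26 in WT and 81.3, 168 and 80.3 in PE- males (log2 difference 2.49, limma adjusted p = 0.0167). FBgn0037807 went the other way, with a log2 difference of -1.22 (limma adjusted p = 0.0111). The call of FBgn0034328 was lost without female WT replicate 2 or 3 (adjusted p = 0.0621 and 0.0535), and that of FBgn0037807 without female WT replicate 3 or PE- replicate 2 (adjusted p = 0.0535 and 0.0527). The interaction test passed for 101 genes, 82 with a more positive change in males and 19 with a more negative one. Of these, 80 were listed at 0 throughout a group, and 13 genes passed when such genes were left out. The count was 1854 after median-of-ratios rescaling, 1679 with FPKM, 1380 after rescaling without the 100 highest genes, 42 with a pseudocount of 0.1 and 43 with a filter of 5 TPM. Leaving out single libraries gave 49 to 1637 genes, the highest without male WT replicate 2 and the lowest without female WT replicate 3, and outside 1.5 times of 101 for all libraries except male WT replicates 1 (81) and 3 (127). Across genes, which are not independent replicates, the PE- effects of the sexes correlated at Pearson 0.1 and Spearman 0.14. In both sexes 5 genes were higher and 29 lower, against 2 and 3 for independent lists. After median-of-ratios rescaling 30 were higher and 58 lower in both, against 13 and 9, and 5 went in opposite directions, against 33.

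WT males differed from WT females in 11285 of 13675 genes, 6734 higher and 4551 lower, and 28 of 29 Y-chromosome genes were higher in males. FBgn0259975 was at 2810, 3060 and 2190 TPM in WT males and at 0.07 TPM or listed at 0 in WT females. FBgn0037844 was at 222, 313 and 243 TPM in females and at 0.901 TPM or listed at 0 in males. FBgn0011761 was at 6030, 7160 and 5990 TPM in WT females and at 3.73, 3.87 and 1120 TPM in WT males, the last being replicate 3. The median log2 change over all genes was 0.61.

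The targeted genes were raised in the libraries that carry their names. SF3B3 (hg38, chromosome 16, 70523816 to 70577668, plus strand) was at 105 ± 4.68 TPM with vector and 579 ± 90.6 with SF3B3 overexpression (SD, n = 3, ratio of means 5.52). SF3B4 (chromosome 1, 149923317 to 149927803, minus strand) was at 146 ± 7.2 TPM with vector and 1190 ± 35.4 with SF3B4 overexpression (ratio 8.18). In the 293T experiment SF3B3 was at 110 ± 2.1 TPM in WT and 988 ± 49.8 with SF3B3-MMS1 (ratio 8.96). The log2 changes were 2.44 (SE 0.1, limma adjusted p = 2.37e-06), 3.02 (SE 0.05, limma adjusted p = 1.02e-10) and 3.15 (SE 0.06, limma adjusted p = 1.32e-06). An exact two-sided permutation test of the TPM values gave p = 0.1 for each, the smallest p that 3 against 3 libraries allow.

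**Figure D1:**
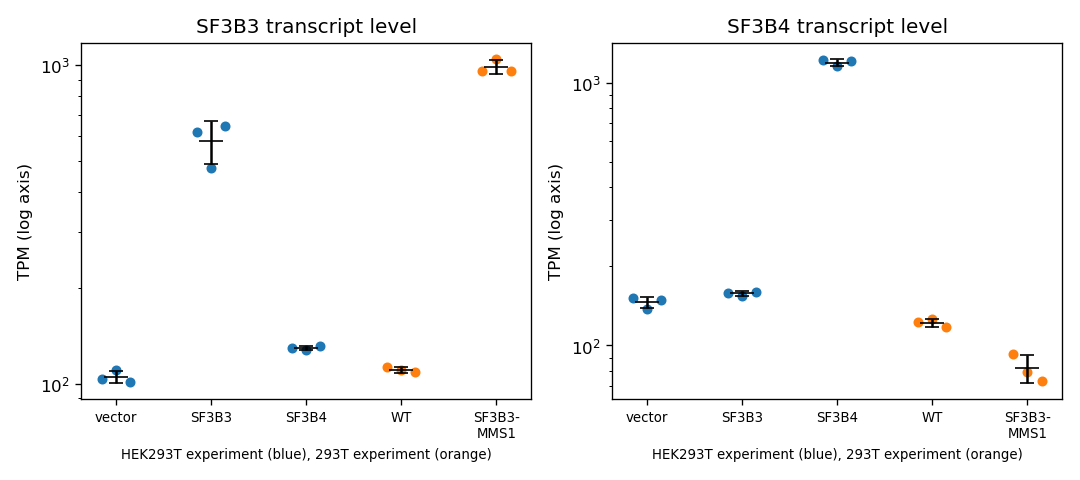
Transcript levels of SF3B3 (left) and SF3B4 (right) in TPM on a log axis, with 1 point per library and the mean with its SD as a black bar, for 3 HEK293T groups (blue) and 2 293T groups (orange). SF3B3 stood at 579 TPM on average with SF3B3 overexpression and 988 with SF3B3-MMS1, and SF3B4 at 1190 with SF3B4 overexpression.

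TPM is a share of a fixed total, and the median change over all tested genes was not 0. It was -0.11 on the log2 scale for SF3B3 against vector, 0.25 for SF3B4 against vector, -0.38 for SF3B3 against SF3B4 and -0.14 for SF3B3-MMS1 against WT. Log2 changes in the following comparisons are given relative to that median, and calls rest on the TPM as deposited. TRNC, a mitochondrial transfer RNA gene, alone held 11.2% to 14.7% of TPM in the vector libraries, 8.33% to 11.3% with SF3B3, 3.43% to 3.73% with SF3B4, 21.4% to 25.4% in 293T WT and 32.1% to 35.8% with SF3B3-MMS1.

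With SF3B3 overexpression, nuclear genes of the respiratory chain and genes of cytosolic ribosomal proteins rose together by small amounts. Of 56 respiratory chain genes 47 rose and 1 fell, and 50 passed when adjusted over the list alone. COX7B and COX5A, subunits of cytochrome c oxidase, went from 52.7 ± 4.65 to 77.6 ± 5.58 TPM and from 266 ± 15 to 346 ± 11.4 TPM (relative log2 changes 0.66 and 0.49). NDUFA8, a subunit of complex I, went from 152 ± 9.92 to 210 ± 13.1 TPM. The list's median stood 0.42 above that of all genes (camera adjusted p = 1.68e-22, but adjusted p = 0.233 with an estimated correlation). Of 64 ribosomal protein genes 40 rose and 0 fell, 50 passed when adjusted over the list alone, 56 rose after rescaling, and the median stood at 0.33 (camera adjusted p = 1.47e-20, adjusted p = 0.299 with an estimated correlation). RPL24 went from 1650 ± 39.8 to 2190 ± 168 TPM and RPL11 from 1110 ± 67.8 to 1400 ± 47.

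Heat shock genes passed as well, with 9 of 18 higher and 1 lower and 10 adjusted over the list alone, or 14 and 0 after rescaling (median 0.27, camera adjusted p = 1.23e-05, adjusted p = 0.299 with an estimated correlation). HSPB1, a small heat shock protein, went from 158 ± 13 to 221 ± 28.8 TPM. Of 21 genes of Sm and other snRNP proteins 8 rose and 3 fell, with 12 adjusted over the list alone, or 13 and 2 after rescaling (median 0.19, camera adjusted p = 0.00375, adjusted p = 0.385 with an estimated correlation). The Sm protein gene SNRPB rose from 826 ± 44 to 1140 ± 124 TPM, while PRPF8 and SNRNP200 of the U5 snRNP fell from 189 ± 17.4 to 120 ± 20.7 and from 155 ± 7.47 to 103 ± 14.4 TPM. In the SF3b complex itself, SF3B3, SF3B5 and SF3B6 rose and SF3B1 fell among 7 members, with 6 passing when adjusted over the list alone (median 0.24, camera adjusted p = 0.00368, adjusted p = 0.233 with an estimated correlation). The list holds the overexpressed SF3B3, so part of this result was set by the design, and the list was not tested without SF3B3. As deposited, its mean log2 change was 0.45 and its median 0.13. SF3B5 went from 377 ± 8.68 to 484 ± 49.9 TPM and SF3B6 from 393 ± 28.9 to 486 ± 30.2. After median-of-ratios rescaling 6 of the 7 members were higher and 0 lower, and the call of SF3B1 was lost (adjusted p = 0.387). Of 10 epithelial markers 3 rose and 0 fell, 3 also when adjusted over the list alone, among them the keratin gene KRT18 from 102 ± 8.17 to 134 ± 7.31 TPM (median 0.26, camera adjusted p = 0.0127, adjusted p = 0.233 with an estimated correlation). Of 24 genes of ATF4 and the unfolded protein response 2 rose and 12 fell, with 17 adjusted over the list alone (median -0.09, camera adjusted p = 0.045, adjusted p = 0.565 with an estimated correlation). Rescaling turned that split to 5 higher and 6 lower. SLC7A11, the cystine transporter, fell from 39.8 ± 2.35 to 21.5 ± 1.94 TPM.

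Among single genes, CYBA, a subunit of NADPH oxidase, rose from 8.15 ± 1.4 to 22.2 ± 1.1 TPM (relative log2 change 1.47, limma adjusted p = 0.000178). NCR3LG1, a ligand of an activating receptor of natural killer cells, fell from 21.8 ± 3.49 to 6.04 ± 2.06 TPM (relative log2 change -1.62). FN1, which encodes fibronectin, fell from 19.4 ± 1.49 to 9.72 ± 0.98 TPM, INSIG1 of sterol regulation from 204 ± 10.1 to 126 ± 0.689, and SMG1, the kinase of nonsense-mediated decay, from 28.1 ± 3.09 to 15.2 ± 1.78. The near-identical ribosomal RNA copies RNA18SN1 and RNA18SN5 had the largest fitted falls but are uncertain, with RNA18SN1 listed at 0 in all but 1 SF3B3 library (79.1 TPM), against 91.3, 127 and 96.5 TPM with vector (limma adjusted p = 0.0243). The call of RNA18SN1 was lost without any 1 of the vector libraries and without SF3B3 replicate 2 or 3 (adjusted p = 0.0519 to 0.0968). Of 15993 tested genes 5900 passed (limma-trend), 1508 higher and 4392 lower, with 20 and 129 of them at least 2-fold. Rescaling by the median of ratios gave 3061 higher and 2751 lower, and 4258 genes passed under both scalings.

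With SF3B4 overexpression, the immediate early genes, which growth factors and stress induce within minutes, rose by large factors. EGR1 went from 33.1 ± 0.411 to 710 ± 12.7 TPM (relative log2 change 4.13, limma adjusted p = 4.38e-11), FOS from 13.5 ± 0.701 to 219 ± 8.19 and FOSB from 2.67 ± 0.251 to 188 ± 3.75. EGR3 was listed at 0, at 0 and at 0.486 TPM in the vector libraries and stood at 75.6, 76.7 and 75.1 TPM with SF3B4. Of 26 list members 21 rose and 1 fell, and 22 passed when adjusted over the list alone. The list's median stood 0.84 above that of all genes (camera adjusted p = 4.28e-06, adjusted p = 0.165 with an estimated correlation).

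Genes of cholesterol synthesis moved down, with 3 of 23 higher and 12 lower and 15 adjusted over the list alone, or 0 and 17 after rescaling (median -0.52, camera adjusted p = 8.55e-09, adjusted p = 0.165 with an estimated correlation). HMGCS1, the HMG-CoA synthase, fell from 65.3 ± 1.58 to 32 ± 1.44 TPM, NSDHL from 81 ± 1.08 to 36.8 ± 1.35 and INSIG1 from 204 ± 10.1 to 79.8 ± 1.87. Of 34 DNA replication genes 25 were higher and 0 lower, 25 also when adjusted over the list alone, among them the helicase subunit genes MCM5 (118 ± 8.01 to 213 ± 2.38 TPM) and MCM4 (233 ± 8.39 to 404 ± 10.1). That list stood only 0.09 above all genes (camera adjusted p = 0.0199, adjusted p = 0.799 with an estimated correlation), and after rescaling 10 members were higher and 6 lower. For hnRNP proteins 18 of 25 genes were higher and 0 lower, 18 adjusted over the list alone, but 4 were higher and 5 lower after rescaling (median 0.01, camera adjusted p = 0.0348, adjusted p = 0.799 with an estimated correlation). PTBP2, a splicing repressor, rose from 21.8 ± 0.848 to 43.6 ± 1.8 TPM.

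Of 56 respiratory chain genes 11 were higher and 12 lower, 23 adjusted over the list alone, with a median of 0.06 as deposited and -0.18 relative to all genes (camera adjusted p = 0.018, adjusted p = 0.799 with an estimated correlation). After rescaling 3 were higher and 32 lower. COX7B fell from 52.7 ± 4.65 to 29.6 ± 0.224 TPM, while ATP5PB of ATP synthase rose from 193 ± 4.35 to 264 ± 7.29. Segments of neighbouring genes also shifted with SF3B4, as described below. The change of a single gene such as COX7B, here and in the comparison with SF3B3, can include that of its segment. For ATF4 and the unfolded protein response 8 of 24 genes were higher and 7 lower, 15 adjusted over the list alone, against 2 higher and 16 lower after rescaling (relative median -0.24, camera adjusted p = 0.0348, adjusted p = 0.799 with an estimated correlation). CHAC1, which degrades glutathione, fell from 121 ± 4.82 to 53.6 ± 4.48 TPM, and the chaperone PDIA4 from 248 ± 2.27 to 140 ± 3.34. Of 5 metallothionein and metal response genes 1 rose and 2 fell, 3 adjusted over the list alone, or 0 and 3 after rescaling (relative median -0.49, camera adjusted p = 0.0251, adjusted p = 0.463 with an estimated correlation), with HMOX1, which encodes heme oxygenase, at 76.6 ± 2.31 and 50.6 ± 1.53 TPM.

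SPARC, a secreted matrix protein, fell from 69.7 ± 2.79 TPM to 0.317, 0.469 and a listed 0 in the SF3B4 libraries (relative log2 change -6.07, limma adjusted p = 5.49e-10). DMD, which encodes dystrophin, fell from 14 ± 1.06 to 0.182 ± 0.0315 TPM and DPYSL3 from 15.6 ± 1.03 to 0.58 ± 0.143. CYBA rose from 8.15 ± 1.4 to 318 ± 12.9 TPM (relative log2 change 4.89, limma adjusted p = 2.63e-10), and COL2A1, the type II collagen gene, from 1.27 ± 0.134 to 41 ± 1.99. The mitochondrial transfer RNA genes TRNV and TRNE fell from 69.7 ± 6.71 to 4.6 ± 0.979 and from 651 ± 111 to 71.4 ± 8.12 TPM. In total 9102 of 15993 genes passed (limma-trend), 7456 higher and 1646 lower, with 1143 and 312 at least 2-fold. Rescaling by the median of ratios gave 3796 higher and 3941 lower, and 5440 genes passed under both scalings.

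Compared directly, without the vector libraries in the contrast, SF3B3 overexpression had higher respiratory chain and lower immediate early expression than SF3B4 overexpression. Of 56 respiratory chain genes 36 were higher and 3 lower, 39 adjusted over the list alone, or 53 and 0 after rescaling, with COX7B at 77.6 ± 5.58 against 29.6 ± 0.224 TPM (median 0.66, camera adjusted p = 6.54e-16, adjusted p = 0.348 with an estimated correlation). Of 26 immediate early genes 2 were higher and 22 lower, 24 adjusted over the list alone, with EGR1 at 22 ± 1.9 against 710 ± 12.7 TPM (median -0.71, camera adjusted p = 0.000169, adjusted p = 0.348 with an estimated correlation). Ribosomal protein genes had 23 of 64 higher and 11 lower, 33 adjusted over the list alone, or 53 and 2 after rescaling (median 0.49, camera adjusted p = 3.15e-08, adjusted p = 0.446 with an estimated correlation). RPL38 was at 760 ± 108 against 319 ± 41.9 TPM, and RPS6 went the other way at 2800 ± 145 against 5030 ± 150.

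For cholesterol synthesis 13 of 23 were higher and 5 lower, 18 adjusted over the list alone, or 19 and 2 after rescaling (median 0.67, camera adjusted p = 8.13e-06, adjusted p = 0.348 with an estimated correlation), with NSDHL at 77.2 ± 2.01 against 36.8 ± 1.35 TPM. Heat shock genes had 9 of 18 higher and 4 lower, 13 adjusted over the list alone, or 16 and 0 after rescaling (median 0.52, camera adjusted p = 0.00106, adjusted p = 0.348 with an estimated correlation), with BAG3 at 40.2 ± 2.33 against 26.4 ± 0.565 TPM. The Sm and snRNP list had 7 of 21 higher and 6 lower, 13 adjusted over the list alone, or 15 and 2 after rescaling, with a deposited median of 0.02, a mean of -0.04 and a relative median of 0.4 (camera adjusted p = 0.0158, adjusted p = 0.348 with an estimated correlation). SNRPD1 was at 80.6 ± 2.68 against 56.1 ± 0.408 TPM and PRPF8 at 120 ± 20.7 against 259 ± 9.67. Of 5 metallothionein and metal response genes 3 were higher and 0 lower, 3 adjusted over the list alone, with MT2A at 68.8 ± 8.49 against 41.4 ± 8.37 TPM (median 0.6, camera adjusted p = 0.0181, adjusted p = 0.348 with an estimated correlation). SPARC was at 69.4 ± 1.13 TPM with SF3B3. In this contrast 11343 genes passed (limma-trend), 2115 higher and 9228 lower, or 5047 higher and 5146 lower after median-of-ratios rescaling, and 7261 passed under both.

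With SF3B3-MMS1 overexpression in 293T cells, the comparison stated in the series design, immediate early genes rose and respiratory chain genes fell. Of 24 immediate early genes 21 rose and 2 fell, 23 adjusted over the list alone, with a median 1.02 above that of all genes (camera adjusted p = 1.75e-12, adjusted p = 0.169 with an estimated correlation). JUN went from 322 ± 14.5 to 856 ± 51.8 TPM (relative log2 change 1.55, limma adjusted p = 2.57e-05), ATF3 from 65.9 ± 2.42 to 177 ± 22.4 and FOS from 14.7 ± 1.36 to 34.3 ± 0.824. Of 56 respiratory chain genes 1 rose and 50 fell, 54 adjusted over the list alone, and 37 fell after median-of-ratios rescaling and 26 after rescaling without the 100 highest genes (median -0.5, camera adjusted p = 1.68e-06, adjusted p = 0.685 with an estimated correlation). CYC1, cytochrome c1, went from 227 ± 15.9 to 149 ± 11.7 TPM.

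Of 25 hnRNP genes 0 rose and 19 fell, 19 adjusted over the list alone, and 14 fell after median-of-ratios rescaling and 9 without the 100 highest genes (median -0.22, camera adjusted p = 0.000162, adjusted p = 0.371 with an estimated correlation), with HNRNPM at 456 ± 15.1 in WT and 211 ± 15 TPM with SF3B3-MMS1. Of 21 Sm and snRNP genes 0 rose and 16 fell, 18 adjusted over the list alone, and 14 and 10 fell under the same rescalings (median -0.3, camera adjusted p = 0.00112, adjusted p = 0.371 with an estimated correlation), with PRPF31 at 123 ± 6.71 and 80.5 ± 3.07 TPM. Other lists of splicing genes did not pass, with 3 of 20 SR proteins and kinases higher and 10 lower, 14 adjusted over the list alone (camera adjusted p = 0.639), or 7 and 10 after rescaling. Of 20 U2 snRNP and branch site factors 1 rose and 12 fell, 14 adjusted over the list alone (camera adjusted p = 0.125), or 4 and 7 after rescaling. The SF3b complex had 1 of 7 higher, the overexpressed SF3B3 itself, and 4 lower, 5 adjusted over the list alone (camera adjusted p = 0.666), or 1 and 2 after rescaling. SF3B4 fell from 122 ± 4.33 to 82 ± 10.2 TPM (relative log2 change -0.43, limma adjusted p = 0.00195). Cholesterol synthesis had 0 of 23 genes higher and 17 lower, 17 adjusted over the list alone (median -0.36, camera adjusted p = 0.000146, adjusted p = 0.336 with an estimated correlation), with LSS, lanosterol synthase, at 95.3 ± 4.28 and 33.9 ± 3.36 TPM. Of 15 NRF2 targets 0 rose and 12 fell, 12 adjusted over the list alone, and 8 and 6 fell under the same rescalings (median -0.25, camera adjusted p = 0.0079, adjusted p = 0.371 with an estimated correlation), with HMOX1 at 58 ± 3.48 and 29.4 ± 4.03 TPM. Of 34 DNA replication genes 2 rose and 18 fell, 20 adjusted over the list alone (median -0.09, camera adjusted p = 0.0306, adjusted p = 0.685 with an estimated correlation), but 3 rose and 10 fell after median-of-ratios rescaling and 6 rose and 6 fell after rescaling without the 100 highest genes. For ATF4 and the unfolded protein response 3 of 24 rose and 15 fell, 19 adjusted over the list alone (median -0.18, camera adjusted p = 0.0345, adjusted p = 0.685 with an estimated correlation), with PSAT1 of serine synthesis at 466 ± 8.96 and 251 ± 21.3 TPM.

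Epithelial markers rose in 7 of 10 genes and fell in 0, 7 adjusted over the list alone (median 0.71, camera adjusted p = 7.43e-05, adjusted p = 0.169 with an estimated correlation). ESRP2, an epithelial splicing regulator, went from 0.393 ± 0.0311 to 9.33 ± 2.03 TPM and KRT8 from 47.7 ± 3.36 to 74.8 ± 3.81. Of 14 genes whose transcripts are known to be sensitive to nonsense-mediated decay 5 rose and 2 fell, 7 adjusted over the list alone (median 0.35, camera adjusted p = 0.00373, adjusted p = 0.477 with an estimated correlation), with GADD45A at 53.9 ± 2.62 and 130 ± 10.6 TPM and GADD45B at 16.2 ± 0.775 and 47.3 ± 2.44. Of 11 replication-dependent histone genes 3 rose and 0 fell, 3 adjusted over the list alone (median 0.41, camera adjusted p = 0.0241, adjusted p = 0.336 with an estimated correlation). The linker histone gene HIST1H1C went from 10.9 ± 0.957 to 26.1 ± 3.02 TPM. Of 17 interferon response genes 7 rose and 3 fell, 11 adjusted over the list alone, or 7 and 1 after rescaling (median 0.19, camera adjusted p = 0.0306, adjusted p = 0.43 with an estimated correlation), with BST2, or tetherin, at 3.58 ± 0.389 and 17.2 ± 1.64 TPM.

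Among single genes, CYBA rose from 2.68 ± 0.515 to 58.3 ± 18 TPM (relative log2 change 4.12, limma adjusted p = 2.57e-05), PLP2 from 0.403 ± 0.232 to 21 ± 3.49 and COL2A1 from 0.359 ± 0.0445 to 10.2 ± 1.04. SMAD6, an inhibitor of BMP signalling, fell from 67.7 ± 2.76 to 14.1 ± 0.431 TPM (relative log2 change -2.04, limma adjusted p = 2.99e-06), and SNAI2, a repressor of epithelial genes, from 61.8 ± 1.52 to 13.6 ± 2.31. XAGE1A and XAGE1B, near-identical copies whose reads are uncertain, fell from 45 ± 0.592 to 7.96 ± 2.49 and from 43.6 ± 0.934 to 7.92 ± 2.44. Of 15558 tested genes 7774 passed (limma-trend), 2279 higher and 5495 lower, with 368 and 271 at least 2-fold. Rescaling by the median of ratios gave 3588 higher and 3520 lower, and 5799 genes passed under both scalings.

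**Figure D2:**
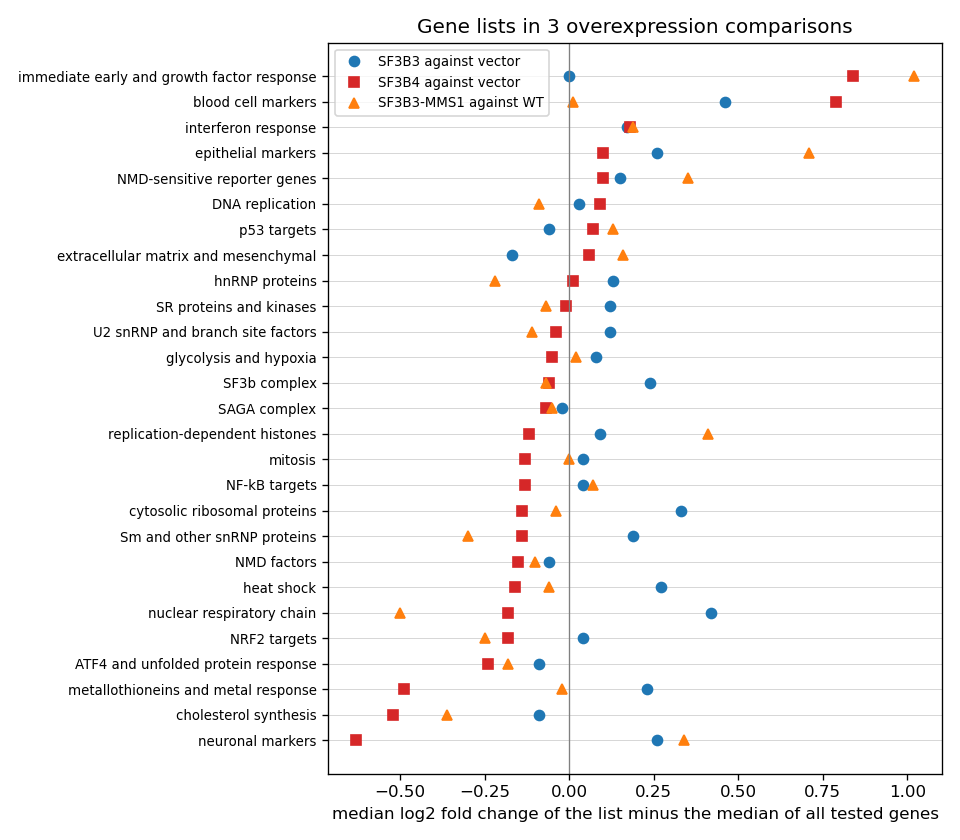
Median log2 fold change of each gene list minus the median of all tested genes, on the horizontal axis, for SF3B3 against vector (blue circles), SF3B4 against vector (red squares) and SF3B3-MMS1 against WT (orange triangles). The immediate early list stood at 0.84 with SF3B4 and 1.02 with SF3B3-MMS1, and the respiratory chain list at 0.42 with SF3B3 and -0.5 with SF3B3-MMS1.

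The changes with SF3B3 and with SF3B3-MMS1 correlated across 15230 genes at Pearson -0.04 and Spearman -0.13. Both overexpressions raised the gene-level value of SF3B3, in separate experiments. Both comparisons called 156 genes higher and 1519 lower, against 213 and 1567 for independent lists. In opposite directions, 851 were higher with SF3B3 and lower with SF3B3-MMS1, against 531, and 561 lower with SF3B3 and higher with SF3B3-MMS1, against 627. After median-of-ratios rescaling both called 456 higher and 562 lower, against 691 and 627, and 1813 went in opposite directions, against 1318. The changes with SF3B3 and SF3B4, measured against the same vector libraries, correlated at Pearson 0.03 and Spearman -0.07. Unchanged groups simulated against those libraries gave 0.5 and 0.46, and the covariance was 0.00736 against 0.0182 simulated, a difference of -0.0109. Both called 615 genes higher and 359 lower, against 703 and 452 for independent lists, while 261 were higher with SF3B3 and lower with SF3B4, against 155, and 2444 the reverse, against 2048. Rescaled by the median of ratios, both called 562 higher and 531 lower, against 727 and 678, and 2076 went in opposite directions, against 1407. Genes are not independent replicates, so no p-value is given.

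NAI-N3, a reagent that acylates the 2'-hydroxyl of flexible RNA nucleotides, and DMSO, its solvent, were given to 293T cells for 10 min, and the series design names a target region of SF3B3 as the aim. There was 1 library of each, so the difference has no replicate check and no test. The libraries held few genes above 0, 171 with NAI-N3 and 63 with DMSO, and 44 in both. SF3B3 was at 11700 TPM with NAI-N3 and 19600 with DMSO, while the other 6 SF3b genes were listed at 0. The 51 genes within 1 megabase of SF3B3 held 17.2% of TPM with NAI-N3 and 48.3% with DMSO. Most of that difference lay in 1 transfer RNA gene, TRG-GCC2-5, with 0.414% and 29%. VAC14 held 6.06% and 6.84%, and MTSS2 4.85% and 6.53%. RN7SK, the 7SK small nuclear RNA, held 19.2% of TPM with NAI-N3 and was listed at 0 with DMSO. Over 190 genes at 1 TPM or more in either library, levels correlated at Pearson 0.04 and Spearman 0.05, and 91.1% differed over 2-fold. Most of these genes were listed at 0 in 1 of the libraries, so no effect of the treatment can be read from these values. The tables hold abundances, so mutation rates are not analysed here.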

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

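The interaction test was planned, and the other splits, the fit without genes at 0 and the tests of male WT replicate 3 were chosen after the results had been seen. The difference between PE- and WT flies varied with sex by the interaction test, which passed for 101 genes. Of 100 drawn splits of the fly libraries, 3, counting the real one, gave as many genes, and the highest other split gave 116. The splits exchange genotype labels within each sex, which also removes any PE- effect common to the sexes. They therefore cannot single out a sex difference, and no conclusion is drawn from that share. Of the 101 genes 80 were listed at 0 throughout a group, and 13 genes passed without such genes. The count therefore rests mostly on genes listed at 0 in a whole group, and whether those zeros are biological or come from the processing of the tables was not tested.

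In male WT replicate 3, which enters that test, 41 further genes stood at a median of 18.2% of the female level. These genes, at 20 to 100 TPM in females and chosen as low in PE- males, were not used to find the pattern. However, their quartiles were 0 and 32.5%, with a highest value of 563%. In WT males 1 and 2 the medians were 0 and 0.0687%, with 4 and 5 of these genes over 10% and highest values of 43.8% and 211%. Of the 40 most abundant genes 27 stood at 10% to 30% and 12 over 50% of the female level. RNA of female flies in the sample therefore stays open, since the medians are equal but the genes do not share 1 level. A female library under a male label is excluded by 585 genes abundant in males. They stood at a median of 69.1% of their level in the other WT males (quartiles 65.8% and 73.4%). Across genes the library correlated with the 6 female libraries at 0.598 on average, against 0.446 and 0.437 for WT males 1 and 2. No biological explanation was tested.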

How the results depend on the processing

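The alternatives below were fixed before the data were examined unless described as added. The comparison of WT sexes and the 4 human comparisons kept their gene counts within 1.5 times under every alternative on all samples. The targeted genes stayed at 2.36 to 2.58, 2.98 to 3.05 and 3.11 to 3.17 when replicates were left out. The fly counts for females, males, average and interaction (85, 2160, 459 and 101) moved to 159, 3774, 2621 and 1679 with FPKM, 193, 3947, 3017 and 1854 with median-of-ratios rescaling, and 242, 3793, 2349 and 1380 without the 100 highest genes. A pseudocount of 0.1 gave 795 in males and 42 for the interaction, and a filter of 5 TPM 43 for the interaction. Only the compared groups gave 144 in females and 88 in males. With the replicate number as a block the average had 870 and the interaction 58 genes. Of the fly libraries 10 of 12 correlated best with their own number, a hint of shared handling in the data, though only at -0.03 to 0.07 (human ones 1 of 9 and 0 of 6). The labels state no pairing, so replicates were treated as unpaired. Added fits without genes at 0 throughout a group gave 242 for the average and 13 for the interaction. Added rescaled fits without male WT replicate 3 gave 3837, 3062 and 1935 for males, average and interaction. Leaving out 1 replicate gave 57 to 71 in females, 794 to 2994 in males, 225 to 2421 for the average, 49 to 1637 for the interaction, 10810 to 11179 between WT sexes, 3994 to 6084 for SF3B3, 7481 to 8519 for SF3B4, 10130 to 11037 between them and 5317 to 7956 for SF3B3-MMS1. The correlation of SF3B3 with SF3B4 was 0.11 with a pseudocount of 0.1, and that of SF3B4 with SF3B3-MMS1 0.31 with that pseudocount and 0.38 with 5 TPM. Leave-one-out gave 0.01 to 0.07 for SF3B3 with SF3B4, -0.12 to -0.02 for SF3B3 with SF3B3-MMS1, 0.06 to 0.13 for the sexes and 0.32 to 0.35 for SF3B4 with SF3B3-MMS1. The lists passing camera (7, 7, 7 and 12) became 0, 0, 0 and 0 with an estimated correlation and 17, 21, 24 and 22 with fry. The fry test asks whether members changed at all, not whether they changed more than other genes. With 36.9% to 70.9% of all genes called, its counts lend no support to the camera results. NAI-N3 and DMSO differed in 98.9% of genes, with a correlation of -0.71, without the 100 highest genes. Only 44 genes were above 0 in both libraries, so such values mostly count genes listed at 0 in 1 library. SF3B2 reversed with SF3B4 to -0.01 (FPKM) and -0.08 (median of ratios), between the overexpressions to 0.09 and 0.22, with SF3B3 to 0.14 (median of ratios) and with SF3B3-MMS1 to 0 (FPKM) and 0.08 (without the 100 highest genes), where PHF5A reversed to 0.03. Under median-of-ratios rescaling SOD2 (-0.06), NFKBIA (0) and RBM8A (-0.01) reversed with SF3B4, and HSPA8 (0), NFKB1 (0.01), ATF4 (0.08) and GCLM (0.01) between the overexpressions. Of all values of named human genes under the alternatives, 1618 of 1689 with SF3B3, 1803 of 1876 with SF3B4, 1872 of 1892 between them and 1691 of 1756 with SF3B3-MMS1 kept direction and side of the threshold. The cause was not tested. The lower depth of SF3B3-MMS1 replicate 2 (1.82 gigabases) limits weakly expressed genes there.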

Other observations

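The list tests and the correlation of SF3B3 with SF3B3-MMS1 were planned, and their use here and the tests of neighbouring genes, of changes shared by SF3B4 and SF3B3-MMS1, of other splits and of genes at 0 were chosen after the results had been seen. Single markers of blood cells and neurons changed with SF3B4 overexpression, while neither list passed. Of 5 blood cell markers 3 rose and 0 fell, 3 adjusted over the list alone (camera adjusted p = 0.401), and of 8 neuronal markers 3 rose and 4 fell, 7 adjusted over the list alone (camera adjusted p = 0.0733). The alpha globin genes HBA1 and HBA2, near-identical copies whose reads are uncertain, rose from 0.337 ± 0.307 to 18.6 ± 1.55 TPM and from 0.384 ± 0.195 to 13.5 ± 0.112 (SD, n = 3). The neurofilament genes NEFL and NEFM fell from 72.2 ± 2.07 to 14.1 ± 1.4 and from 56 ± 0.836 to 10.5 ± 0.222 TPM, while INA, which encodes another neuronal intermediate filament, rose from 9.52 ± 0.423 to 37.5 ± 1.37. With SF3B3-MMS1, NEFM rose from 60.2 ± 0.721 to 201 ± 11.9 TPM, GDF15, a secreted stress factor, from 1.39 ± 0.0511 to 11.3 ± 1.22, and the cell cycle inhibitor gene CDKN1A from 30.9 ± 2.42 to 79.1 ± 2.58.

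Neighbouring genes shifted together, most with SF3B4 overexpression. In 627 windows of 20 neighbouring genes the medians of the log2 changes had an SD of 0.235, against at most 0.104 in 1000 shuffles of gene order. The SD was 0.153 (at most 0.102) with SF3B3-MMS1 and 0.105 (at most 0.093) with SF3B3. Genes of 109493606 to 110963962 on chromosome 1 had a median of 1.41 with 17 of 20 higher, and those of 102712176 to 106797016 on chromosome X a median of -1.06 with 17 of 20 lower. Noise of weakly expressed genes is excluded, because the SD was 0.242 over genes of at least 20 TPM. What shifts these segments stays open, since copy number was not measured and no biological explanation was tested.

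The changes with SF3B4 and with SF3B3-MMS1 overlapped, although the groups come from separate experiments. Both called 1437 genes higher and 1003 lower, against 1014 and 579 for independent lists, and 1921 were higher with SF3B4 and lower with SF3B3-MMS1, against 2532, and 129 the reverse, against 232, with a Pearson correlation of 0.35. After median-of-ratios rescaling both called 1429 higher and 1654 lower, against 797 and 896. Then 835 went in opposite directions, against 1693, and the correlation was again 0.35. A few strong genes do not account for it, with a Spearman correlation of 0.34, nor do shared chromosome segments, with 0.39 after subtracting the window medians over 11632 genes, against 0.4 before on the same genes. Whether a higher SF3B3 level as such plays a part was not decided. The changes with SF3B3 and SF3B3-MMS1 correlated at -0.04, but those comparisons differed in their controls and in the SF3B3 level reached. In the SF3B4 libraries SF3B3 was at 129 ± 1.99 TPM, against 105 ± 4.68 with vector. That is a log2 change of 0.3 as deposited and 0.04 after median-of-ratios rescaling. Some segments did rise in both. On chromosome 13, genes of 111114619 to 114327328 had a median of 0.8 with SF3B4, and those of 106541673 to 113864076 had 0.72 with SF3B3-MMS1. On chromosome 8, the windows that start at 37736579 stood at 0.82 and 0.37. The windows with the largest falls lay on different chromosomes. What else the cells share was not found, and a difference in handling between overexpressing and control cells was not tested.

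Other splits of the same libraries were refitted. For the average over the sexes 1 of 100 splits, the real one, gave as many genes, and the highest other gave 145. For 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. The real split alone reached its gene count, 1 of 10, in females (highest other 7), males (12), WT sexes (3), SF3B3 (2), SF3B4 (1), SF3B3 against SF3B4 (1) and SF3B3-MMS1 (1). For the list tests it was 1 of 10 with SF3B3 (highest other 5) and SF3B3-MMS1 (8), and 2 of 10 with SF3B4 (7) and SF3B3 against SF3B4 (8).

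Genes listed at 0 in 1 library of a group, with at least 10 TPM in each of the others, numbered 28 to 65 per fly library, 1 to 4 per HEK293T library and 0 to 8 per 293T library.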
